A study of Mus musculus with 2 samples.

How the data were processed

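Total RNA of the left cerebral cortex of B6CASTF1/J mice aged 18 to 20 months was sequenced as 2 long-read libraries of a single group, per the labels. The deposited values are whole-number counts of reads per transcript, not normalized, with each transcript named and classed against GENCODE M21 on mm10, per the file headers. The transcript attributes are those of TALON, per the file headers; its version, the aligner and the sequencing platform are not given in the sources used here. Each library has its own transcript models, and every listed transcript has at least 1 read. Names of unannotated models were therefore not compared between libraries. The labels give male in a structured entry and female in a free-text description, so no library was assigned a sex, and they list 1 donor entry with separate tissue entries, so the libraries were not treated as separate animals. Spike-ins named in the labels are the Lexogen SIRV set with long SIRVs and Ambion ERCC mix 1.

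Replicate 1 held 1187511 reads and replicate 2 held 1118251. Reads of annotated genes numbered 1040787 and 1023031, reads of genes outside the annotation made up 11.2% and 7.47%, spike-in reads 1.19% and 1.05%, and mitochondrial reads 0.0792% and 0.116%. A single read was 0.842 and 0.894 CPM, where CPM (counts per 1e6 reads) is the count over all reads of the file. A count of 0 allows up to 3 reads, or 2.53 and 2.68 CPM. This limit per library was used for the CPM limits and least fold differences printed for genes with 0 reads. Log2 ratios, and the medians and fold cutoffs taken from them, used the prior given below instead, also for genes with 0 reads.

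Gene counts were sums over the transcripts of a gene. Agreement between libraries was described by Pearson and Spearman correlation of log2(CPM + 1) and by the common dispersion of edgeR 4.0.16 with an intercept only, in R 4.3.3. Each gene with at least 20 summed reads was tested by an exact two-sided binomial test of its reads given the library totals, with Benjamini-Hochberg adjustment at 0.05, and log2 ratios of replicate 2 to replicate 1 used a prior of 0.5 reads. Alternatives were TMM factors from edgeR, DESeq2 1.42.0 size factors, no filter or at least 50 summed reads, known transcripts only, mitochondrial genes and spike-ins left out of the total, and a threshold of 0.01. TMM moved all log2 ratios by -0.07.

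Transcript classes were those of the files, with exact 95% binomial intervals; alternatives kept transcripts with at least 3 reads, spliced transcripts, or left out mitochondrial genes and spike-ins. Unannotated spliced transcripts were matched between libraries by chromosome, strand and every intron, with alternatives allowing 10 nt at each splice site or asking for 3 reads in each library. Detection was counted at 1, 3 and 10 reads, also after thinning the deeper library and with known transcripts only. Isoforms were joined between libraries by annotated name or intron chain, with the unannotated unspliced reads of a gene pooled. The leading isoform was tested against all others of its gene by Fisher's exact test in genes with at least 50 reads in each library; alternatives were 20 or 100 reads, known transcripts only, incomplete splice matches left out, and a threshold of 0.01.

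Inclusion of an internal exon was the share of reads joining it to both neighbours among these and the reads joining the neighbours directly, with at least 20 spanning reads in each library, tested between libraries by Fisher's exact test. Exons with mean inclusion from 10 to 90% are described, split into microexons of 3 to 27 nt and longer exons; alternatives were 50 spanning reads, known transcripts only, and transcripts with at least 3 reads. Pairs of such exons on the same molecule were tested in the genes of the isoform list by Fisher's exact test in each library with at least 30 reads, and called where both libraries passed in the same direction; alternatives were 100 reads, known transcripts only, and transcripts with at least 3 reads. Spike-ins and transcript lengths were also summarised with known transcripts only, and lengths without mitochondrial genes and spike-ins. Summaries per library alone stand for leaving out the other replicate.

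For 31 lists with 352 names, covering cell types, brain regions, cortical layers, synaptic and receptor genes, early response genes, aging glia, energy metabolism, imprinted, long noncoding and sex-linked genes and genes with brain isoforms, members with at least 20 summed reads were tested, and the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression. Lists were also run with TMM factors and with known transcripts only. The lists, tests and alternatives above, and the rule for named genes, were fixed before the data were examined. The rule takes the 10 most abundant genes, up to 4 members per list by mean CPM and all members of lists of 5 or fewer, up to 10 called genes per side by log2 ratio among those with at least 50 summed reads, 15 isoform genes by mean CPM, the 10 most abundant unannotated spliced transcripts (listed without incomplete splice matches), 10 genes led by an unannotated isoform (the pooled unspliced class not counted), the 5 genes with the most isoforms, 10 microexons, 10 longer exons and 10 exon pairs by reads. Called members of lists are named beside it, and some genes that the rule takes are not reported here.

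Chosen after seeing the data were a further striatal list, list members with at least 50 summed reads, random lists matched also on transcript length, counts without the striatal lists, and all same-strand reads over the exons of the called genes more than 4-fold apart. The same holds for the assignment of unannotated models to genes by 1 rule in both libraries, since the same intron chain was at times filed under different genes, and for leaving out incomplete splice matches together with unannotated unspliced reads. That assignment moved 0.31% of reads in replicate 1 and 0.265% in replicate 2.

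The gene test was tried on simulated counts for 10220 genes: it called 35 of 50 genes raised 2-fold, 50 of 50 raised 4-fold, 17 of 45 lowered 2-fold, 33 of 46 lowered 4-fold and 7 of 10029 left as they were. In all simulations reads were drawn independently, so the libraries differed by sampling of reads alone. The real libraries differed more, with a chi-square per gene of 1.92, so the simulation does not give the rate of false calls in them. The pair test called 100 of 100 coordinated and 0 of 100 independent pairs, and the inclusion test 100 of 100 exons set to 30 and 70% and 1 of 100 set alike. Computation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures matplotlib 3.10.9.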

Results

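The series measured RNA of the left cerebral cortex of B6CASTF1/J mice, the F1 hybrid of C57BL/6 and CAST, aged 18 to 20 months, by long-read sequencing, in which a read covers much or all of a transcript. The labels give 1 group with 2 libraries, replicate 1 and replicate 2, each made from 2 µg of RNA. They list a single donor entry and separate tissue entries, and do not say whether the tissue came from separate animals. A structured label says male and a free-text description says female, so no sex was assigned to either library. Replicate 1 held 1187511 reads assigned to 162958 transcripts, and replicate 2 held 1118251 reads assigned to 147679 transcripts. No comparison of conditions exists in this design. The comparisons are between the libraries, and between transcripts, exons and gene groups within them. Intervals and upper limits cover counting error only, since reads of amplified cDNA need not be independent molecules.

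Among the most abundant genes, the polyubiquitin gene Ubb (ENSMUSG00000019505.7, chromosome 11, 62551171 to 62553213, mm10) had 4714 ± 93.6 CPM, reads scaled to the library total (SD, n = 2), the lipid carrier Apoe 4184 ± 28.7 and the calmodulin gene Calm2 3942 ± 58.3. Then came the glycolytic enzyme Aldoa with 3238 ± 186 CPM, the prohormone-processing enzyme Cpe with 3203 ± 156, the prostaglandin synthase Ptgds with 2889 ± 49.0, the synaptic SNARE protein Snap25 with 2867 ± 252, the chaperone Hspa8 with 2761 ± 29.9 and the brain creatine kinase Ckb with 2716 ± 119.5. The processed pseudogene Gm15459, which shares 93.5% of its 25-nt words with Hspa8, had 2405 ± 86.7 CPM.

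Among 10198 genes with at least 20 summed reads, 196 differed between the libraries by an exact two-sided binomial test with Benjamini-Hochberg adjustment at 0.05, 141 higher and 55 lower in replicate 2. Protein-coding genes made up 178 of them. The split of directions moved with the scaling: TMM factors gave 88 higher and 82 lower, and DESeq2 size factors gave 82 and 91. Known transcripts only gave 122 and 20. The library totals of the main test include reads of genes outside the annotation, 11.2% in replicate 1 and 7.47% in replicate 2. The test compares the reads of these libraries, not animals or conditions. Of the 196 genes, 60 differed by over 2-fold and 27 by over 4-fold. At an unadjusted p under 0.05 the count was 1270, and the chi-square per gene was 1.92, where sampling of reads alone gives about 1. The biological coefficient of variation by edgeR was 9.54%. Across these genes, which are not independent replicates, log2 CPM had a Pearson r of 0.955 and a Spearman rho of 0.952.

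**Figure D1:**
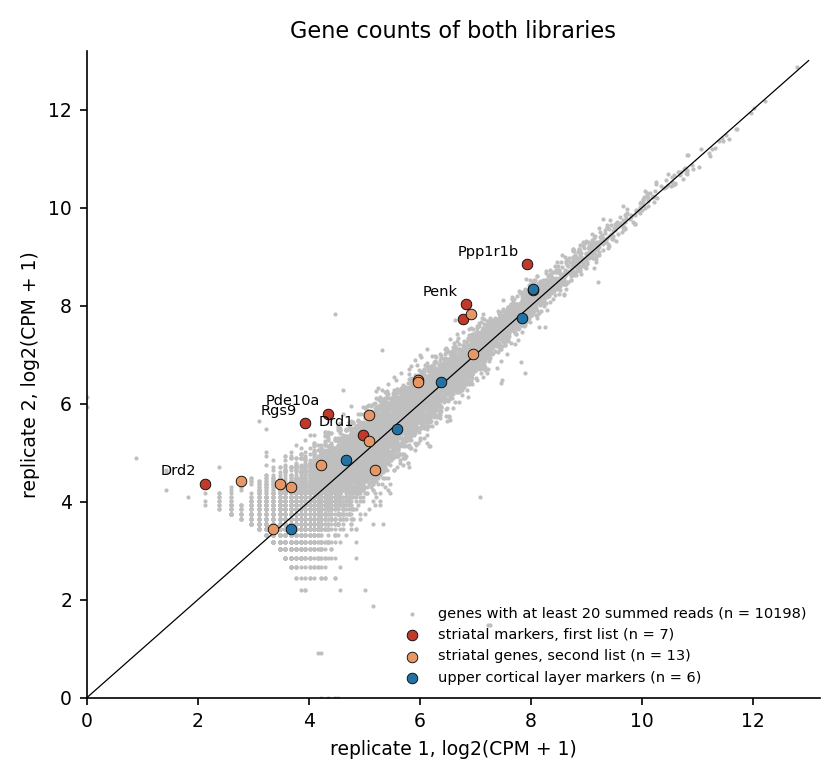
Each point is a gene with at least 20 summed reads, at log2(CPM + 1) in replicate 1 (x axis) and replicate 2 (y axis), and the line marks equal values. Red points are striatal markers, some of them named, which sat above the line in 7 of 7 cases, orange points are genes of a further striatal list and blue points are upper cortical layer markers.

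Called genes higher in replicate 2 with at least 50 summed reads included Rgs9 and Pde10a of the striatal list, and Rxrg, Syndig1l and Lrrc10b, which are in neither striatal list. The retinoid receptor gene Rxrg had 10 reads in replicate 1 and 49 in replicate 2 (log2 ratio 2.32). In the same order, the signalling regulator Rgs9 had 17 and 53 (1.70) and Syndig1l had 28 and 86 (1.69). The phosphodiesterase gene Pde10a had 23 and 61 (1.47) and Lrrc10b had 17 and 53 (1.70). Also on this side were Pcdhga2, a clustered protocadherin with 0 and 78 reads (at least 27.6-fold higher against a floor of 3 reads in the library), 2310075C17Rik with 0 and 67 (at least 23.7-fold), Gm45837 with 25 and 254, Cdkl3 with 9 and 55 and Ccdc159 with 46 and 152. When every unannotated transcript was assigned to genes by 1 rule in both libraries, an alternative chosen after seeing the data, 2310075C17Rik had 128 and 67 reads and was lower in replicate 2 by the test, Ccdc159 13 and 11, and Cdkl3 9 and 5. Under that rule Pcdhga2 still had 0 and 78 reads and Gm45837 had 25 and 247, and both still differed by the test. Counting every same-strand read over the exons of the gene, likewise chosen afterwards, gave 476 and 523 reads at Pcdhga2 and 500 and 615 at Gm45837.

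Called genes lower in replicate 2 included the glucocorticoid-induced gene Tsc22d3 (282 and 110 reads, log2 ratio -1.27), the major histocompatibility class I gene H2-K1 (45 and 16, -1.38) and Kdsr, an enzyme of sphingolipid synthesis (45 and 17, -1.29). Gm21887 had 159 and 18 reads (-3.02), the antisense genes Gm17202 47 and 12 (-1.84) and Gm20687 51 and 19 (-1.31), and the pseudogene Gm7805 41 and 12 (-1.64). BC065397 had 182 and 2 reads, Gm11223 177 and 2, and Agap2 65 and 28. Under the single assignment rule BC065397 had 2 and 2 reads, Gm11223 177 and 151, and Agap2 30 and 15, none of which differed by the test or had enough reads for it. That rule gave 176 genes in all, 131 higher and 45 lower, of which 167 were among the 196, and 21 over 4-fold apart. It kept 16 of the 27 genes over 4-fold apart.

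Markers of medium spiny neurons, the main cell type of the striatum, were higher in replicate 2. The median log2 ratio of the striatal list was 1.20, with 7 of 7 tested members higher and 6 called (6 adjusted over the list alone), and its median lay at the 100 percentile of 10000 random lists matched on expression. The dopamine and cAMP phosphoprotein gene Ppp1r1b had 288 and 514 reads (log2 ratio 0.92, adjusted p = 9.64e-16 by the exact binomial test) and the enkephalin precursor Penk 134 and 290 (1.20, 1.58e-13). The dopamine receptor genes had few reads: Drd2 4 and 22 (2.41), which was called, and Drd1 36 and 45 (0.40), which was not. A further list of striatal genes, written after this result was seen, had a median of 0.52 at the 99.98 percentile, with 12 of 13 members higher, 1 called (Pde1b, 142 and 255 reads) and 3 adjusted over the list alone. Its most abundant gene, Ptpn5, had 309 and 356 reads, Kcnip2 had 146 and 144, and Gnal 73 and 99. Without the members of both striatal lists 189 of the 196 called genes were left. Only genes named in these lists were taken out, so the 189 can still hold other striatal genes.

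The thalamic list had a median of 1.06 at the 99.885 percentile over only 3 tested genes, none called (2 adjusted over the list alone): Slc17a6 with 14 and 28 reads, Lef1 with 10 and 22 and Rora with 86 and 60; Prkcd (9 and 9) and Tcf7l2 (6 and 7) had too few reads. The hippocampal list had a median of 0.41 (percentile 99.25), with 1 of 2 members called, Wfs1 (238 and 322 reads), and 2 adjusted over the list alone, the other being Calb1 (311 and 362). Fibcd1 had 11 and 8 reads. The olfactory list had a median of -1.16 (percentile 1.35): Doc2g, with 27 and 4 reads, was called (1 adjusted over the list alone), Cdhr1 had 12 and 13, Th 3 and 1 and Eomes 0 and 0. Upper layer markers of cortex (Calb1, Lamp5, Cux1, Cux2) had a median of -0.01 and deep layer markers (Rprm, Fezf2, Ccn2, Bcl11b) a median of -0.19, with no member called in either list; adjusted over the list alone the counts were 1 and 0. With known transcripts only the upper layer median was 0.30.

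**Figure D2:**
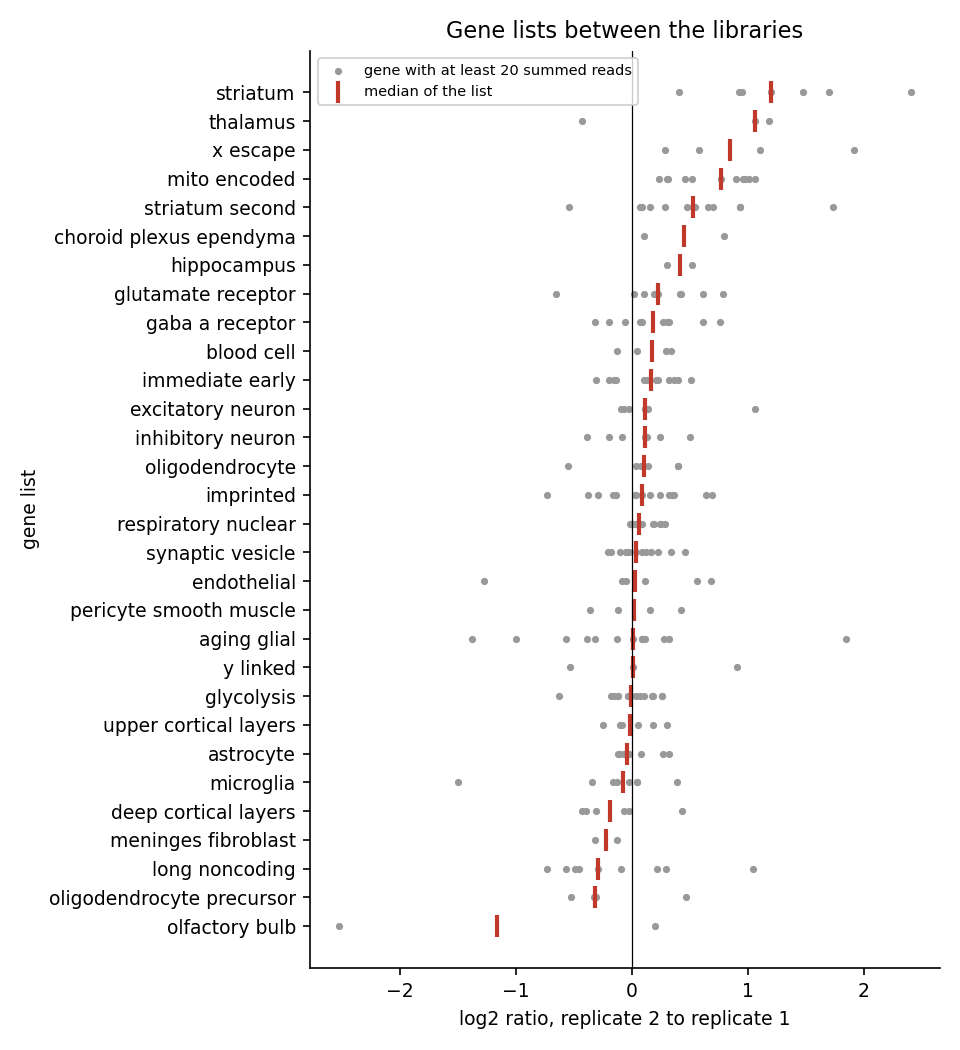
Each grey point is a list member with at least 20 summed reads, placed at its log2 ratio of replicate 2 to replicate 1 (x axis), with 1 line per list (the further striatal list included, the isoform list left out) and the median as a red bar. The striatal list has its median at 1.20 and the long noncoding list at -0.29.

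Summed over the list, markers of excitatory neurons had 3977 ± 8.30 CPM, led by Nrgn (2299 ± 102), the vesicular glutamate transporter Slc17a7 (1246 ± 68.9), Camk2a and Tbr1, and inhibitory markers had 952 ± 55.2, led by Gad1 (409 ± 48.0), Lamp5, Vip and Npy. Astrocyte markers had 3632 ± 2.11 CPM, led by Aldoc, Slc1a3, Gja1 and Slc1a2, and oligodendrocyte markers had 2783 ± 151, among them the myelin genes Mbp (1766 ± 32.7), Cnp and Mobp. The median log2 ratios of these lists were 0.12, 0.11, -0.04 and 0.11. The members called were 0, 0, 1 (Slc1a3, 618 and 700 reads) and 1, and adjusted over the list alone the counts were 0, 0, 2 and 1. Under the single assignment rule 0 oligodendrocyte markers were called, with a median of 0.08. Microglial markers (among them Csf1r, Ctss and C1qa) had 670.1 ± 16.9 CPM and a median of -0.07, and oligodendrocyte precursor markers (Olig1, C1ql1, Pdgfra, Cspg4, Vcan) had 138 ± 8.87 CPM and a median of -0.32; no member of either was called, also adjusted over the list alone. With known transcripts only the median turned to 0.53 in the precursor list, 0.17 in the astrocyte list and 0.01 in the microglial list.

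Endothelial markers had 1281 ± 32.1 CPM, of which Bsg, also present in other cells, had 975 ± 38.3 and the tight junction gene Cldn5 211 ± 11.4; Slco1a4 and Ly6c1 followed, with none called and 1 adjusted over the list alone. Pericyte and smooth muscle markers (Rgs5, Vtn, Pdgfrb, Acta2) had 179.7 ± 11.4 CPM, meningeal fibroblast markers (Dcn, Col1a1, Col1a2, Lum, Igf2) 49.0 ± 0.986, choroid plexus and ependymal markers (Enpp2, Ttr, Kl, Ccdc153) 229 ± 20.2, and blood markers (Hba-a1, Hbb-bs, Hba-a2, Hbb-bt, Alas2) 223 ± 3.93. Their median log2 ratios, with the endothelial list first, were 0.03, 0.02, -0.22, 0.45 and 0.17. No member of the last 4 lists was called, also adjusted over the list alone, and with known transcripts only the pericyte median was -0.20.

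Synaptic vesicle genes together had 11009 ± 78.8 CPM, led by Snap25, Vamp2 (1761 ± 46.6) and Syp (1343 ± 55.2). Snap25 was lower (log2 ratio -0.18) and Sv2b higher (0.46) in replicate 2 by the test, and 5 of 13 members passed adjusted over the list alone; the list's median was 0.04. Glutamate receptor genes (Grin1 500 ± 4.05 CPM, Gria2 321 ± 29.6, Gria1, Gria4) had a median of 0.23 and GABA-A receptor genes (858 ± 73.2 CPM in sum, Gabrd among them) a median of 0.18, with no member called; adjusted over the list alone the counts were 1 and 0. Immediate early genes, which neurons switch on with activity, had 1693 ± 12.4 CPM, led by Arc (394 ± 37.8), Junb, Egr1 and Egr4, with a median of 0.17, none called and 0 adjusted over the list alone.

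Energy metabolism genes were abundant. Glycolytic genes had 14259 ± 5.80 CPM, led by Aldoa, Pkm (1980 ± 255), Aldoc and Ldhb, with a median of -0.01; Pkm was higher (0.26) and Aldoa lower (-0.12) by the test, and 3 passed adjusted over the list alone. Nuclear genes of the respiratory chain (Cox4i1, Atp5b, Atp5a1, Uqcrc1) had 7882 ± 319 CPM and a median of 0.06, with none called and 0 adjusted over the list alone. Genes encoded in mitochondria had only 938 ± 247 CPM. Their median log2 ratio was 0.77 at the 100 percentile, with 11 of 11 higher in replicate 2, 4 called (mt-Nd2, mt-Nd5, mt-Rnr2 and mt-Rnr1) and 8 adjusted over the list alone; mt-Co1 had 370.3 ± 56.8 CPM and mt-Cytb 83 and 92. With the single assignment rule 3 were called.

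Of 9 tested long noncoding RNAs 2 were lower in replicate 2 by the test and 7 were not called, 3 of the 9 having a higher value in replicate 2; the list's median log2 ratio was -0.29 at the 0.165 percentile. The imprinted transcript Meg3 (700 and 397 reads, -0.73, adjusted p = 2.29e-13 by the exact binomial test) and Snhg11 (333 and 211, -0.57) were called, 3 of 9 passed adjusted over the list alone, and Miat (170 and 114) and Peg13 (117 and 135) followed in abundance. Imprinted genes had 4758 ± 91.0 CPM and a median of 0.09: Meg3 and Snrpn (2020 and 1704 reads) were lower and Impact (164 and 241) higher by the test, 3 passed adjusted over the list alone, and Gnas (1643 ± 69.2 CPM) and Ndn were not called. Genes of aging and reactive glia had 5502 ± 60.7 CPM, mostly Apoe, and Ctsd (638 ± 39.2), Gfap (185 ± 29.3) and H2-D1 came next. H2-D1 (211 and 99 reads) and H2-K1 were lower and complement C4b (10 and 35 reads, 1.84) was higher in replicate 2; the list's median was 0.01 and 3 passed adjusted over the list alone. With known transcripts only its median was -0.14 at the 0.44 percentile.

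Genes of the Y chromosome were read in both libraries and Xist was not. Ddx3y had 58 and 55 reads (49.0 ± 0.242 CPM), Eif2s3y 54 and 35, Uty 10 and 18 and Kdm5d 8 and 5, in sum 105 ± 5.96 CPM, or 34.3 with reads of known transcripts only. Xist and its antisense gene Tsix had 0 reads in each library, which allows up to 2.53 CPM in replicate 1 and 2.68 in replicate 2. The list of X inactivation RNAs had no gene to test. By known transcripts only, Ddx3y had 24 and 23 reads, Eif2s3y 13 and 13, Uty 3 and 0 and Kdm5d 1 and 2. Females carry no Y chromosome, so the Y-linked reads argue against either library holding RNA of female animals alone. X-linked partners that escape inactivation had a median log2 ratio of 0.84 at the 99.97 percentile, with 4 of 4 higher in replicate 2, none called and 2 adjusted over the list alone: Eif2s3x (46 and 53 reads), Kdm5c (24 and 34), Ddx3x (17 and 35) and Kdm6a (5 and 19). No member of the Y-linked list was called, also adjusted over the list alone, and its median was 0.01.

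Most reads followed known transcripts. Known transcripts held 64.8 ± 2.68% of reads (SD, n = 2) but 14.5 ± 0.794% of the transcripts listed, since a known transcript had 32.8 and 33.4 reads on average in the libraries. Incomplete splice matches, classed in the files as parts of a known transcript, held 10.1 ± 0.182% of reads. Of these reads 69.6% and 68.7% lacked the 5' part, and 19.1% and 20.9% were unspliced and so carried no intron. New combinations of known splice sites held 6.72 ± 0.0508%, transcripts with a new splice site 4.01 ± 0.179%, and reads running into introns or other unannotated sequence of a gene, classed genomic, 5.55 ± 0.509%. Reads antisense to annotated genes held 9.94% in replicate 1 (exact 95% interval 9.888 to 9.996) and 6.37% in replicate 2 (6.32 to 6.41), and intergenic reads held 0.730 ± 0.0605%. Of the antisense reads 98.2% and 97.8% were unspliced; among spliced transcripts only, the antisense share was 0.202%.

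**Figure D3:**
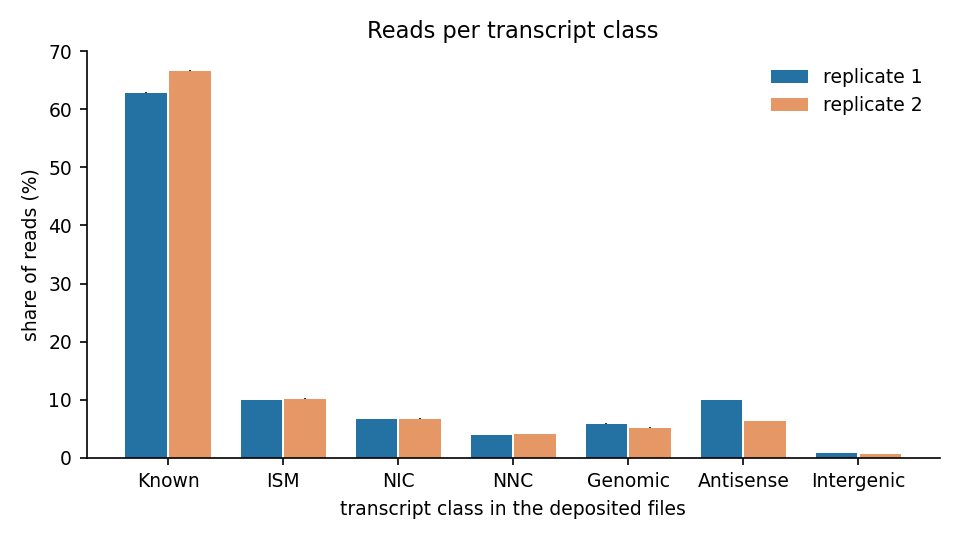
Bars give the percent of each library's reads (y axis) in each transcript class (x axis), blue for replicate 1 and orange for replicate 2, with exact 95% binomial intervals too narrow to see at this depth. Antisense reads made up 9.94% in replicate 1 and 6.37% in replicate 2.

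With incomplete splice matches left out, the most abundant unannotated splice patterns found in both libraries belonged to the postsynaptic calmodulin-binding gene Nrgn (2172 ± 89.3 CPM, 94.5 ± 0.296% of the gene's reads), the polyamine regulators Oaz1 (986 ± 25.6) and Oaz2 (429 ± 12.4), the amyloid precursor adaptor Apbb1 (508 ± 60.2), the septin gene Sept7 (466 ± 10.6), the lipid transfer gene Pitpna (423 ± 45.0), the vesicle gene Rab3a (401 ± 14.0), Ctbp1 (379 ± 55.4), Aplp2 (347 ± 41.1) and the neuronal hydrolase Uchl1 (268 ± 20.6). The Nrgn transcript carried 1 unannotated intron, on chromosome 9 from 37545349 to 37545947, joining an unannotated site to an annotated one. In all, with incomplete splice matches counted, replicate 1 had 98167 and replicate 2 had 92563 unannotated intron chains, of which 33659 were identical in chromosome, strand and every splice site, 8314 of them with at least 3 reads in each library. Incomplete splice matches, which are parts of known chains, made up 37211 of the chains in replicate 1 and 16475 of the identical ones. Of the chains with 1 read in replicate 1, 20.6% were found in replicate 2 (exact 95% interval 20.3 to 20.9), of those with 2 reads 52.9%, with 3 to 9 reads 83.8% and with at least 10 reads 99.9%. By class, the 1-read share was 28.9% for incomplete splice matches, 21.4% for new combinations of known sites and 12.4% for chains with a new site.

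Reads covered 17358 annotated genes in replicate 1 and 17040 in replicate 2, with 15373 in both. With at least 10 reads the counts were 10345 and 10159, with 9669 in both. With spike-ins left out and the unannotated unspliced models of each gene pooled, 59802 transcripts were shared, out of 157757 and 144131. Transcripts with a single read were 60.8% and 61.5% of those listed, and with the deeper library thinned to the total of the other 15313 genes were found in both.

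In most genes a single isoform led. Across 4288 genes with at least 50 reads in each library, the most abundant isoform held a median of 71.2% of the gene's reads (70.2% in replicate 1 and 72.3% in replicate 2), and the libraries had the same leading isoform in 94.7% of genes. The leading isoform was known in 3740 genes. Unannotated spliced forms led in Nrgn (94.5 ± 0.296%), Oaz1 (95.1 ± 0.693%), Apbb1, Sept7 (86.5 ± 0.0339%), Ctbp1, Aplp2 and the RNA-binding gene Hnrnpk (33.7 ± 1.37%), and incomplete splice matches led in the mitophagy kinase Pink1 (53.9 ± 4.89%), the phospholipase-like gene Pld3 (79.1 ± 1.47%) and Nell2 (58.5 ± 0.475%). The genes with the most isoforms of at least 3 reads in each library were a gene on an unplaced scaffold (42), the splicing regulator Celf4 (34), Ndrg4 (31), Adgrb2 (27) and Kifc2 (26).

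Isoform use differed between the libraries in 27 of the 4288 genes by Fisher's exact test with Benjamini-Hochberg adjustment at 0.05, and in 361 at an unadjusted p under 0.05. Genes with the smallest p values included Plppr2 (leading isoform 35.6% in replicate 1 and 86.7% in replicate 2), the phosphodiesterase gene Pde2a (28.3% and 58.3%), the phosphatase gene Ppp2ca (93.0% and 99.2%) and Pkm (86.4% and 79.6%). Under the single assignment rule 20 genes differed, 17 of them among the 27. Pde2a still did, with 28.3% and 57.1%, and the others named did not: Plppr2 had 31.7% and 41.3%, Ppp2ca 93.0% and 93.6% and Pkm 80.9% and 79.6%. Pde2a overlaps Gm45837 on chromosome 7, which still had 25 and 247 reads under that rule, while Pde2a had 459 and 336 as deposited. Whether reads of Pde2a filed under Gm45837 account for the difference in Pde2a was not tested. With known transcripts only no gene differed, and 92 did at an unadjusted p under 0.05.

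In the fixed list of genes with brain isoforms, the leading isoform held a median of 44.2% across 69 tested genes; the difference from all genes was not tested. Leading shares were 91.0 ± 0.00336% in the G protein gene Gnas, 89.1 ± 0.180% in Aldoa, 83.0 ± 4.77% in Pkm, 81.0 ± 1.85% in Apoe, 80.8 ± 0.913% in Snap25, 78.0 ± 1.36% in App, 71.5 ± 0.936% in the calcineurin gene Ppp3ca, 70.9 ± 0.379% in Rtn3, 63.6 ± 1.08% in Mbp, 57.7 ± 2.35% in Rtn1, 47.7 ± 3.51% in Ndrg4, 43.8 ± 1.27% in Camk2b and 40.9 ± 1.41% in Ndrg2. The leading form of App, the amyloid precursor, was App-201. In Mbp the leading Mbp-211 was followed by Mbp-212 with 12.5 ± 0.577%, and in Rtn1 Rtn1-202 held 30.9 ± 2.32%. Of the 69 genes 4 differed between libraries (6 adjusted over the list alone), and by gene counts 9 of the list's 84 tested genes differed, 7 higher and 2 lower in replicate 2 (15 adjusted over the list alone, median log2 ratio 0.14). Under the single assignment rule 8 genes of the list differed by gene counts.

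Of 1902 internal exons with mean inclusion from 10 to 90%, 72 were microexons of 3 to 27 nt, with a median inclusion of 68.0% (64.5% in replicate 1 and 70.2% in replicate 2), and 1829 were longer, with 57.5% (56.4% and 59.0%). A length that is a multiple of 3, which keeps the reading frame, was found in 84.7% of microexons (exact 95% interval 74.3 to 92.1) and 53.5% of longer exons (51.2 to 55.8; two-sided Fisher's exact test, p = 4.99e-08, with exons as units that are not independent replicates). Microexons among those with the most reads lay in Snap91 (15 nt, included in 87.3 ± 1.32%), the kinase gene Mink1 (24 nt, 85.7 ± 4.24%), the receptor gene Cd47 (25 nt, 83.9 ± 0.0529%), Bin1 (24 nt, 82.4 ± 0.935%), Trim9 (24 nt, 81.5 ± 5.50%), the dynactin gene Dctn1 (21 nt, 80.4 ± 3.55%), Pls3 (27 nt, 76.2 ± 1.82%), Nckap1 (18 nt, 55.0 ± 1.07%) and the phosphatase gene Ptpra (27 nt, 53.2 ± 1.42%). All of these are fully coding in the annotation.

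Longer exons among those with the most reads showed strong preferences. In Snap25 the 118-nt exon on chromosome 2 from 136770057 to 136770174 was included in 88.4 ± 0.903% and its 118-nt partner in 11.6 ± 0.839%. In Pkm the 167-nt exon of the muscle and brain form was included in 89.2 ± 0.802% and its 167-nt partner in 10.7 ± 0.720%. A 30-nt exon of Ppp3ca was included in 79.6 ± 0.457%, a 39-nt exon of Ndrg4 in 83.1 ± 1.95%, a 42-nt exon of Ndrg2 in 31.3 ± 1.93%, a 123-nt exon of Mbp in 16.8 ± 0.631% and a 120-nt exon of the proteolipid gene Gpm6b in 16.3 ± 0.496%. Inclusion in the libraries had a Pearson r of 0.952 across exons. By Fisher's exact test 3 exons differed, named here after their values were seen: Stoml2 (65.9% and 100%), Eef1d (33 of its spanning reads in replicate 1 and 0 of 56 in replicate 2) and Pcyt2 (51.6% and 76.9%), and 87 at an unadjusted p under 0.05. Under the single assignment rule no exon differed by Fisher's exact test, and 84 did at an unadjusted p under 0.05: Stoml2 had 65.9% and 72.0%, Eef1d 33 reads with and 70 without in replicate 1, and 18 and 66 in replicate 2, and Pcyt2 the same values with an adjusted p of 0.0516 by Fisher's exact test.

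**Figure D4:**
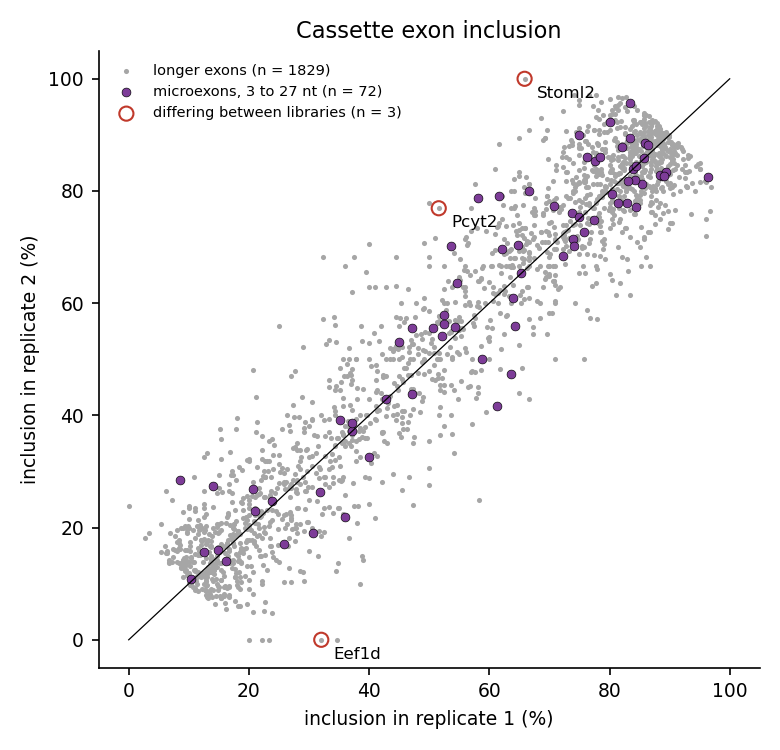
Each point is an exon with mean inclusion from 10 to 90%, at its inclusion in percent in replicate 1 (x axis) and replicate 2 (y axis), purple for the 72 microexons and grey for the 1829 longer exons, with a line at equal values. Red rings mark the 3 exons that differed as the genes are named in the files.

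Of 74 pairs tested in 27 genes of the fixed list, 38 pairs in 17 genes passed Fisher's exact test in both libraries in the same direction, 25 together and 13 apart. Bin1 alone gave 14 of the 25, some of them overlapping forms of the same exons, so 11 together and 13 apart were left in the other genes. Mutually exclusive use was seen in the Snap25 pair, where 0.0470 ± 0.0166% of molecules had both exons or neither, in the Pkm pair with 0.0428 ± 0.0606%, in the 76-nt exons of the tropomyosin gene Tpm3 with 0.691 ± 0.585%, and in the 115-nt flip and flop exons of the AMPA receptor genes Gria2 with 2.69 ± 0.926% and Gria1 with 0.800 ± 1.13%. In the NMDA receptor gene Grin1 the 111-nt exon of the C-terminal tail and the 63-nt exon of the N-terminal domain lie far apart. They were on the same molecule less often than independent choice would give, with both or neither in 39.9 ± 1.84% (adjusted p by Fisher's exact test 0.00153 and 0.0035 in the libraries).

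Other pairs went together. In the adhesion gene Cadm1 an 84-nt and a 33-nt exon had the same choice in 73.7 ± 5.47% of molecules, in the clathrin light chain gene Clta a 54-nt and a 36-nt exon in 78.8 ± 0.725%, in the membrane-bending gene Bin1 a 24-nt and a 108-nt exon in 55.8 ± 1.72% and in the membrane skeleton gene Epb41l3 a 528-nt and a 36-nt exon in 34.0 ± 1.16%. In Bin1 the 108-nt exon was read without the 24-nt exon on 2 molecules of replicate 1 and 0 of replicate 2, out of 260 and 284. In Epb41l3 the 528-nt exon was read without the 36-nt exon on 0 of 161 and 0 of 169 molecules. Of the tested pairs 5 passed in replicate 1 only and 6 in replicate 2 only, and no pair passed in opposite directions.

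Spike-in RNAs held 1.19% of reads in replicate 1 and 1.05% in replicate 2. Of the 96 ERCC transcripts in the annotation 49 had a read, 42 in replicate 1 and 46 in replicate 2, and the 4 most abundant held 85.9 ± 0.637% of the spike-in reads. Across spike-ins, the log2 counts of the libraries had a Pearson r of 0.977 and a Spearman rho of 0.936. The SIRV spike-ins that the labels name were not analysed here.

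Assigned reads had a median transcript length of 2290 nt in replicate 1 and 2383 nt in replicate 2. Transcripts under 1 kb held 9.79 ± 0.302% of reads, those of 1 to 2 kb 29.5 ± 1.65%, those of 2 to 3 kb 27.6 ± 0.266%, those of 3 to 4 kb 17.2 ± 0.542% and those of at least 4 kb 15.9 ± 1.07%.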

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

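The test of the striatal list against all genes, the test of its members with at least 50 summed reads, the tests with random lists matched on length and with a further striatal list, the test of sequence beside antisense models and the test with 1 rule of assignment were chosen only after the patterns were seen. Reads of unannotated models on the strand opposite annotated genes are summed into no gene tested in the report. They do count in the library totals that scale the gene comparisons. At the loci below they stood far above the 2.53 and 2.68 CPM that a count of 0 allows. Opposite Gm26917, a long noncoding gene on chromosome 17, reads averaged 9655 ± 1307 CPM (SD, n = 2; 12563 and 9764 reads), against 43 and 38 reads of the gene itself. Opposite the noncoding gene Snhg11 they averaged 2429 ± 1058 CPM, opposite the astrocyte glutamate transporter Slc1a2 2074 ± 223, opposite the synaptic scaffold gene Shank1 1173 ± 152 and opposite AI593442 675 ± 36.02. Slc1a2 had 349 and 317 sense reads and Shank1 63 and 33.

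Among 1306 antisense loci with at least 20 reads, 1139 had more in replicate 1, with a median log2 ratio of -0.78. For unspliced antisense models inside 1 annotated exon, the 20 nt of genome beyond their 3' end had a median A share of 0.5, against 0.3 at random positions of the same exons, a difference of 0.2. In the sense direction the difference was -0.013, but sense reads given the wrong strand can end at true polyadenylation sites with no A stretch in the genome, and 35.5% and 36.4% of spliced antisense reads mirror annotated introns, so this explanation stays open. Priming on A-rich stretches of the opposite strand also stays open and may account for part of these models; the test covers 308 of the 2741 models with at least 10 reads, the others were not searched, and no biological explanation was tested.

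Markers of medium spiny neurons of the striatum had a median log2 ratio of 1.20 in replicate 2 against replicate 1. The median of all tested genes, which library scaling moves alike, was 0.0777, the list's median was 1.07 over members with at least 50 summed reads, and its percentile was 100 among random lists matched also on length, which argues against library scaling, few reads and transcript length as the whole cause. More striatal tissue in the block of replicate 2 is a candidate explanation that stays open: a further list sharing no member had a median of 0.52 at the 99.98 percentile. The most abundant genes of that list were not alike, with Ptpn5 at 309 and 356 reads, Pde1b at 142 and 255 and Kcnip2 at 146 and 144, against Ppp1r1b at 288 and 514 in the striatal list; all 8 genes of the striatal list had reads in both libraries, and the labels name no sort. Other lists also had medians above 0, with 1.06 in the thalamic list, 0.41 in the hippocampal, 0.77 in the mitochondrially encoded and 0.84 in the X escape list. The thalamic median rests on 3 tested genes, 2 higher and 0 called, with sums of 105 and 113 CPM, and the hippocampal on 2 tested genes, 1 called. Of the 4 X escape genes 0 were called. The antisense share was 9.94% in replicate 1 and 6.37% in replicate 2, and a difference between animals was not tested.

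Of the 27 called genes more than 4-fold apart, 17 were still called and 16 still more than 4-fold apart when unannotated models were assigned to genes by 1 rule in both libraries. This argues against the filing of such models under different genes as the whole cause. For single genes it may account for the difference: BC065397 went from 182 and 2 reads to 2 and 2, and Gm11223 from 177 and 2 to 177 and 151. With all same-strand reads over the exons summed, the median absolute log2 ratio was 0.57 against 3.48, and of 21 genes with an overlapping model 17 were under 2-fold and 3 over 4-fold apart, but this sum leaves out some of the genes' own reads and takes in those of neighbours. Reads shared between overlapping annotated transcripts therefore stay open, and no biological explanation was tested.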

How the results depend on the processing

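The settings without striatal lists, with 1 assignment rule, and with unannotated unspliced reads left out were chosen only after the results were seen. No paired analysis was possible because the series holds 1 group. At a threshold of 0.01, 117 genes differed in counts and 16 in isoform use. Known transcripts held 72.4% of reads among transcripts with at least 3 reads and 76.1% among spliced transcripts, where antisense reads held 0.202%. Asking for 3 reads in each library left 8314 shared unannotated intron chains, incomplete splice matches included. The median leading share was 67.2% at 20 reads per gene, 74.6% at 100 reads, 98.6% with known transcripts only and 81.9% without incomplete splice matches. Isoform use differed by Fisher's exact test in 0 genes with known transcripts only (92 at an unadjusted p under 0.05), in 123 without incomplete splice matches, and in 14 of 3534 when unannotated unspliced reads were left out as well. Exons with inclusion from 10 to 90% numbered 832 at 50 spanning reads, 544 with known transcripts only and 1128 among transcripts with at least 3 reads. In the same order the median inclusion of microexons was 75.1%, 72.4% and 72.3%, and of longer exons 52.1%, 52.4% and 53.9%. Exons differing by Fisher's exact test numbered 0 with known transcripts only (24 at an unadjusted p under 0.05), 7 among transcripts with at least 3 reads and 0 with 1 assignment rule (84 at an unadjusted p under 0.05). At 100 reads 20 exon pairs were called, and Y-linked genes had 34.3 CPM with known transcripts only.

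Of the remaining values, 188 were counted as unchanged and 15 smaller ones moved, among them the shares of directions given in the report. Values of 1 library alone were unchanged by construction, since with 2 libraries each lies within 1 SD of their mean, so they test nothing. Counts were taken as unchanged within a set fold of the main value, and list medians on the same side of the percentile limits. The median of aging and reactive glia was -0.14 with known transcripts only, at the 0.44 percentile, against 0.01 with all reads. With TMM factors the medians of the endothelial, pericyte, synaptic vesicle, aging glia, nuclear respiratory and Y-linked lists turned from just above 0 to values from -0.06 to -0.01. The genes differing numbered 176 and the isoform genes 20 with 1 assignment rule, where the median leading share was 71.1%. Lists left with fewer than 2 tested members gave no value with known transcripts only. The cause of the moved values was not tested, apart from the class names described in the last part.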

Other observations

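The counts of this part were chosen only after the results were seen, apart from the 123 genes without incomplete splice matches, an alternative fixed beforehand. Processed pseudogenes held many reads that match abundant housekeeping genes. Gapdh, the glycolytic dehydrogenase, had only 38 and 23 reads in replicates 1 and 2, while its pseudogenes Gm12671 had 464 and 473, Gm12033 306 and 258, Gm5559 234 and 243, and Gm7336 212 and 191. Gm12671 shares 100% of its 25-nt words with Gapdh, and Gm12033 and Gm5559 share 97.4%. Gm10123, which shares 100% with the cyclophilin gene Ppia, had 879 and 897 reads against 921 and 1004 of Ppia, and Gm15459 had 2929 and 2621 against 3304 and 3064 of the chaperone gene Hspa8. Other such pairs were Rpl3-ps1 (378 and 342 reads) with the ribosomal gene Rpl3 (870 and 910), and Gm10698 (168 and 176) with the trafficking gene Tmed2 (249 and 234). Levels of these genes, including Gapdh in the glycolytic list, depend on where such reads were placed, which was not tested.

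Spliced antisense models held 2.74% and 2.92% of the reads of antisense genes, and 35.5% and 36.4% of those spliced reads lay in models whose every intron is identical to an annotated intron on the other strand. Unspliced antisense reads opposite the synaptic gene Cplx2 were higher in replicate 2 (569 and 980 reads), unlike most other antisense loci.

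Unannotated unspliced reads of the same gene had different class names in each library. In 121 of 696 genes (17.4%) over 90% of them were named incomplete splice match in 1 library and genomic in the other. The synaptic gene Cplx2 had 302 such reads named genomic in replicate 1 and 279 named incomplete splice match in replicate 2, Ncdn 236 and 246, and Ywhag 223 incomplete splice match and 206 genomic. The 123 genes differing in isoform use without incomplete splice matches, against 14 without either kind of read, are consistent with this naming. Models with the same introns were also filed under different genes. Assigning them by 1 rule moved 3679 and 2961 reads, of which 1664 and 1364 went between annotated genes.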
